A study of Rattus norvegicus with 4 samples.

How the data were processed

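The study measured gene expression in the soleus, a slow postural hindlimb muscle, of male Wistar rats fed a control diet or the same kind of diet with genistein, a soy isoflavone that binds oestrogen receptors. Per the labels, rats were 10 weeks old at the start, the genistein diet held 0.05% genistein (0.5 g per kg of diet), and diets were fed for 24 days. On day 14 the left sciatic nerve was severed and the right leg was sham-operated, and muscle was taken 10 days later. Total RNA of 8 animals was pooled per group, and each of the 4 pools (control diet sham, control diet denervated, genistein diet sham, genistein diet denervated) was labelled with biotin and hybridised to 1 Affymetrix rat array. The sham and denervated pools of a diet come from opposite legs of the same rats.

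The authors deposited 1 linear signal intensity per probe set and array, and the submitters' processing notes name GCOS version 1.1, Affymetrix's operating software. No detection calls were used here, and the scaling target is not given in the sources used here. The mean deposited intensity after removal of 2% of the probe sets at each end was 500.2 on each of the 4 arrays, so the signals were used as scaled by the authors, with no further normalization in the main results. The signals were taken as linear because they are positive and span several orders of magnitude. The treatment-group field of 2 of the 4 samples contradicts their titles, source names and descriptions (the control diet denervated sample carries a sham label and the genistein diet sham sample a denervated one). Groups were taken from the titles, and the muscle genes that respond to nerve loss are given first in the report because they check these labels.

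Each array holds 31099 probe sets, of which 57 controls were set aside. The platform annotation paired 20826 probe sets with 1 gene symbol, 436 with several and left 9780 without a listed gene. Only probe sets with 1 symbol were named, and 20758 of their gene identifiers matched the annotation of the GRCr8 rat assembly, with 0 symbols updated. Each of the resulting 14217 genes was represented by its probe set with the highest mean log2 signal over the 4 arrays, and the values of its other probe sets are given for genes whose probe sets differ by more than 1 log2 unit in a cited ratio (for denervation, on the control diet). No genome build is given in the sources used here, so no coordinates are reported.

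Signals below the 40th percentile of all non-control probe sets on the 4 arrays together (78.9 units) were raised to that floor before taking log2. A gene counted as measured in a comparison when at least 1 of the arrays compared was above the floor, and a ratio with 1 side at the floor is a lower bound. With 1 array per group there are no replicates, so no test was run and no p-value is given, and genes are not replicates of each other. Genes were counted by a fixed size of 2-fold, which is a statement about these 4 arrays and not about the diets or the operation in other animals. The number of arrays limits the precision. As a guide to measurement scatter, the log2 ratios of a gene's probe sets were set against their mean, over 2310 genes with 5373 probe sets. Their SD about that mean was 0.35 for the denervation effect on the control diet and 0.36 on the genistein diet. For the diet effect it was 0.26 in sham muscle and 0.25 in denervated muscle. Probe sets of a gene share the same arrays, so this SD leaves out scatter between pools.

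Before the data were examined, 29 gene lists with 495 members were written down, of which 452 members were on the array: muscle and metabolic groups, signalling and stress groups, and markers of the other cells that whole muscle holds. The median log2 ratio of each list's measured members was placed among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes where a list stands on these arrays, and a list counted as outside the central 95% below percentile 2.5 or above percentile 97.5. Medians were given for lists with at least 5 measured members. The genes named were the 10 highest and the 10 lowest ratios of each comparison among genes above the floor on every array compared, ranked for the shared denervation effect by the smaller of the 2 ratios. A set of genes of muscle wasting, oestrogen signalling and myosin type was named in any case, as were the list members with the largest ratios. Names without an established symbol were passed over. Where any gene was chosen after its values were seen, the text says so.

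The comparisons were the denervation effect within each diet, the diet effect within sham and within denervated muscle, and the difference between the denervation effects of the diets. The diet effect in denervated muscle and the denervation effect on the control diet share the control denervated array with opposite sign, which produces a negative relation with no diet effect at all. That relation was therefore set beside 100 simulated sets of arrays built with no diet effect. Their scatter was drawn as normal. Its size at each signal level was a robust SD, from the median absolute deviation of the difference between the 2 sham arrays. The simulated levels were means of the 2 measured sham or denervated arrays, which hold scatter of their own. The counting was also tested on simulated data for the denervation effect on the control diet, with all 14217 genes in the step and 50 genes at each size. The changed genes were drawn from those with a mean sham signal more than 1 log2 unit above the floor, so the rates do not cover dimmer genes. The counting called 50% of genes built with a true 2-fold change, which equals the threshold, 92% at 2.83-fold and 100% at 4-fold. Of 10851 unchanged measured genes, 92 (0.848%) passed 2-fold in 1 diet and 4 (0.0369%) in both diets.

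Alternatives fixed beforehand were no floor, floors at the 20th and 60th percentiles, scaling to the median, quantile normalization, the mean of a gene's probe sets, removal of probe sets that may cross-hybridise, and a size of 1.5-fold. Scaling to the bacterial and phage hybridisation controls was added after seeing the data, because those controls were lower on both denervated arrays. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Probe sets with several genes or no listed gene were left out of all gene counts.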

Results

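Gene expression was measured in the soleus of male rats on a control or a genistein diet, 10 days after the sciatic nerve of one leg was severed and the other leg was sham-operated. There were 4 groups, each a pool of RNA from 8 rats on 1 array, so no value below has a replicate or an error of its own. The median deposited signal was 128 units for control diet sham, 121 for control diet denervated, 130 for genistein diet sham and 133 for genistein diet denervated muscle. Between 58.5% and 60.8% of probe sets lay above the floor of 78.9 units on each array. Across the 9362 genes above the floor on all 4 arrays, log2 signals correlated at 0.989 between the sham arrays, at 0.985 between the denervated arrays, and at 0.912 to 0.918 between a sham and a denervated array. The 100 brightest probe sets held 13.4% and 12.5% of the signal in control and genistein sham muscle and 10.5% and 9.32% in the denervated muscles.

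The genes that check the sham and denervated labels separated the denervated from the sham pools in both diets. Chrna1, the muscle acetylcholine receptor alpha subunit, was at 1860 units in control sham and 20550 in control denervated muscle, and at 1589 and 16186 on genistein. Chrng, the fetal gamma subunit of that receptor, was below the floor in both sham pools and at 881 and 1046 units in the denervated pools, at least 11.2-fold higher on the control diet and at least 13.3-fold on genistein. Myog, the myogenic transcription factor induced by nerve loss, was 3.52-fold and 4.26-fold higher. These values go with the sample titles and against the treatment field of the 2 samples in which the labels conflict. They do not check which diet an array belongs to, which was taken from the titles alone.

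The first question is what loss of the nerve did to the soleus in each diet. Denervated muscle had far more mRNA for the type IIb myosin and parvalbumin and for markers of nerve loss, and less for the slow sarcomere and mitochondrial energy metabolism. Myh4, the fast type IIb myosin heavy chain, was at 82 units in control sham muscle and 18730 in control denervated muscle (log2 ratio 7.84), and at 144 and 11286 units on genistein (6.30). Pvalb, the calcium buffer parvalbumin of fast fibres, was higher by 4.93 and 5.77 log2 units on the control and genistein diets. Perm1, a muscle regulator of oxidative metabolism, was lower by log2 ratios of -6.17 and -6.44, and Ankrd2, a stretch-responsive ankyrin protein of slow fibres, by -5.97 and -6.16. All 13 measured denervation markers were higher in both diets, 12 of them at least 2-fold, with a list median of 2.52 on the control diet and 2.90 on genistein.

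Among the denervation markers, Myod1 had log2 ratios of 3.43 and 3.63 on the control and genistein diets, Gadd45a 3.25 and 3.52, and Cdkn1a, the cell cycle inhibitor p21, 3.26 and 3.34. Hdac4, a histone deacetylase that relays loss of nerve activity, was higher by 3.45 and 2.90. Other genes with large ratios in both diets were Emb (4.82 and 5.50), Sncg (4.30 and 4.02), Ppp1r14c (3.63 and 4.14) and Dclk1 (3.62 and 4.48). The glutathione transferases Gstt3 (4.10 and 4.50), Mgst2 (4.31 and 3.87) and Gstm2 (3.60 and 3.62) were also higher, whereas their relative Mgst3 was lower (-4.25 and -3.84). Armc9 was higher by 4.94 and 4.34 on its brightest probe set, but its 3 probe sets ranged from 0.02 to 4.94 on the control diet. The lactate transporter Slc16a3 was lower (-4.50 and -5.12), as were Mettl21c (-4.12 and -3.93), Myoz3 (-3.92 and -3.91), Adamts8 (-3.90 and -4.21), the transferrin receptor Tfrc (-3.87 and -4.01) and Acss1, a mitochondrial acetyl-CoA synthetase (-3.85 and -4.27). Also among the 10 highest or lowest ratios of 1 diet were Irx3 (3.91 and 3.60), Aif1l (3.71 and 3.37), Klk1 (3.52 and 4.69), Tmem100 (3.52 and 4.53), Adap2 (3.56 and 4.02), Nmrk2 (-4.53 and -3.47), Ramp1 (-4.18 and -3.80) and Endou (-4.35 and -4.10). On the control diet the probe sets of a gene also disagreed for Irx3 (2.81 to 3.91), Aif1l (1.24 to 3.71), Tmem100 (0.56 to 3.52), Cdkn1a (3.26 to 4.69), Dclk1 (1.69 to 3.62), Ppp1r14c (2.57 to 3.63) and Myoz3 (-3.92 to -1.07), and for genes given below, Mybpc2 (1.30 to 2.64), Igfbp5 (1.26 to 2.92), Hspb7 (-2.61 to -1.57) and Trib3 (1.48 to 2.94).

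**Figure D1:**
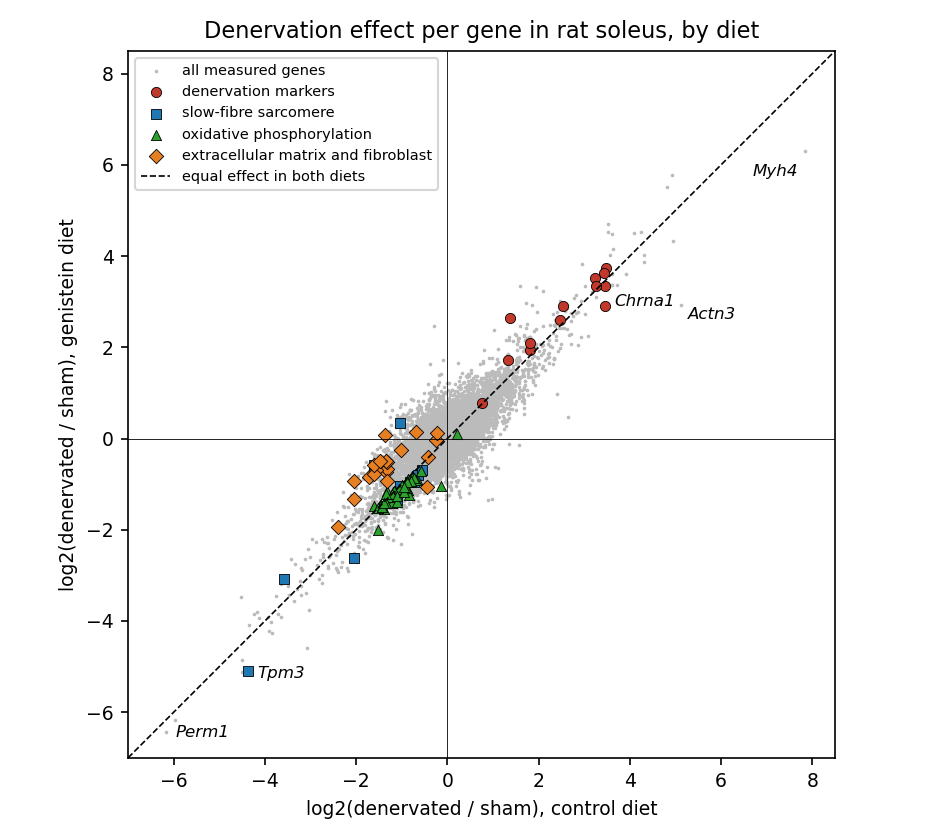
Log2 ratio of denervated over sham signal per gene on the control diet (horizontal) and on the genistein diet (vertical), 1 pooled array per group, with the members of 4 gene lists marked and the dashed line showing equal effects. Most genes lie along the line (correlation across 9362 genes 0.861), Actn3 and Myh4 lie below it, and the extracellular matrix genes lie above it with medians of -1.35 on the control diet and -0.62 on genistein.

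The median of the slow-fibre sarcomere genes in denervated muscle was -1.08 on the control diet, with 8 of 12 members at least 2-fold lower, and -0.99 on genistein with 6 of 12. Under quantile normalization the medians were -0.59 and -0.42, and the genistein value came inside the central 95% of random lists. Casq2, the slow and cardiac calsequestrin, had log2 ratios of -3.58 and -3.08 on the control and genistein diets, and Myl2, the slow regulatory light chain, -2.05 and -2.63. Tpm3, slow tropomyosin, was at -4.37 and -5.09 on its brightest probe set, while its 12 probe sets ranged from -4.37 to -0.03 on the control diet. Myh7, the slow myosin heavy chain, was lower by only -0.73 and -0.95 on a probe set that read 48928 units in control sham muscle, and its other probe set gave -2.05 and -2.67. Fast-fibre genes had no common direction. Actn3, the fast alpha-actinin, was higher by 5.12 and 2.92, and Mybpc2, fast myosin-binding protein C, by 2.64 and 0.46. Myh2, the type IIa myosin, was lower (-1.58 and -1.22), and the probe sets of Myh1, the type IIx myosin, disagreed between -0.99 and 1.01 on the control diet. The median of the 15 fast-fibre genes, -0.29 and -0.36, turned positive under quantile normalization (0.15 and 0.17) and spike-in scaling (0.10 and 0.12).

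Energy metabolism was lower across several pathways. Of 45 oxidative phosphorylation genes, 26 on the control diet and 35 on genistein were at least 2-fold lower, with medians of -1.10 and -1.17, and Cyc1 (-1.52 and -1.52) and Ndufb8 (-1.51 and -2.01) among the lowest. The medians of 14 citric acid cycle genes were -1.04 and -1.12, with Mdh2, mitochondrial malate dehydrogenase, at -1.55 and -1.64. Fatty acid uptake and oxidation genes had medians of -0.99 and -1.29, with 12 and 19 of 24 at least 2-fold lower, led by Hadh (-3.22 and -2.83). Ucp3, the muscle uncoupling protein, went the other way (1.36 and 1.49). Glycolysis and glycogen genes were lower too (-0.82 and -0.96), including the insulin-responsive glucose transporter Slc2a4 (-1.95 and -2.26). The regulators of these pathways had medians of -0.57 and -0.79, with Ppargc1b at -2.01 and -1.58, Sirt3 at -1.78 and -1.76, Esrra at -1.40 and -1.71 and Ppargc1a, the coactivator of mitochondrial biogenesis, at -0.57 and -0.78. Each of these 5 medians was below percentile 1 of the matched random lists in both diets and stayed negative under every scaling tried.

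Genes of protein breakdown went both ways. Trim63, the muscle ubiquitin ligase MuRF1, was 2.33-fold higher on the control diet and 2.29-fold on genistein, and Fbxo32, the ligase atrogin-1, was 1.97-fold and 1.54-fold higher. Fbxo30 was higher by log2 ratios of 2.72 and 2.58, while Mul1 was lower (-0.89 and -1.31). The 11 ubiquitin ligases had medians of 0.43 and 0.42, which came inside the central 95% of random lists under quantile normalization and with the mean of probe sets. None of the 30 proteasome subunit genes passed 2-fold, yet 26 on the control diet and 25 on genistein were above 0, with medians of 0.23 and 0.30. The autophagy and lysosome list had medians of 0.11 and 0.20, and its control diet value became -0.02 under median scaling. Its members diverged, with the cathepsin Ctsl higher by 1.22 and 1.11 and the muscle calpain Capn3 (-1.72 and -1.50) and Bnip3 (-0.97 and -1.16) lower. In the insulin-like growth factor, Akt and FoxO group, Foxo1 was higher by 1.42 and 0.78, Foxo3 by 0.24 and 0.16, Pik3r1 by 2.38 and 2.17 and Igfbp5 by 2.32 and 1.63. Igf1 was lower on the control diet (-0.80) and near its sham level on genistein (-0.06). The list medians were 0.39 and 0.10, the second of which became -0.02 under median scaling.

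Other signalling and stress groups also differed from sham. In the myostatin and TGF-beta list (medians 0.20 and 0.44), the antagonist follistatin Fst was higher by 3.27 and 3.11 and Inhba was lower at -2.25 and -1.70, while Mstn was below the floor on all 4 arrays. Antioxidant genes had medians of 0.64 and 0.59, with Nqo1 at 2.20 and 1.85, Hmox1 at 1.56 and 1.79 and Gpx1 at -1.38 and -1.36. Heat shock and small chaperone genes had medians of -0.73 and -0.61, with Hspb7 at -2.61 and -2.30 and Hspb6 at -2.07 and -2.13. Clock genes had medians of -0.43 and -0.30, with Npas2 at -1.63 and -1.45, and the genistein value became 0.18 under spike-in scaling. The endoplasmic reticulum stress list had medians of -0.41 and 0.05, the second of which turned negative under median scaling and quantile normalization, and held Trib3 at 2.94 and 2.23. The neuromuscular junction list lay near 0 (-0.10 and -0.07, positive under quantile and spike-in scaling), with Lrp4 at 2.34 and 2.49 and Colq at -1.33 and -1.30. The oestrogen list had medians of 0.47 and 0.01, the second negative under median and quantile scaling, and its members Myc (1.76 and 1.53) and Vegfa (-2.10 and -2.06) went opposite ways. Esr1 and Esr2, the oestrogen receptors alpha and beta, were below the floor on all 4 arrays, with Esr1 at 3.3 to 8.0 units and Esr2 at 3.6 to 11.3.

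Markers of cells outside the fibre were mostly lower in denervated muscle on the control diet and less so on genistein. Extracellular matrix and fibroblast genes had medians of -1.35 on the control diet, with 15 of 20 at least 2-fold lower, and -0.62 on genistein with 3 of 20, and Col1a1 was at -2.40 and -1.94. Endothelial genes had medians of -1.02 and -0.38, the second 0.05 under spike-in scaling, and Kdr was at -1.84 and -0.89. Macrophage and leukocyte genes had medians of -0.45 and 0.21, and adipocyte genes -0.13 (0.24 under spike-in scaling) and 1.12. Schwann cell and nerve genes had medians of -0.11 (0.19 under spike-in scaling) and 0.35. Satellite cell markers had medians of -0.63 and -0.50. Erythrocyte genes had a median of -0.58 on the control diet, with only 4 measured members on genistein. Cell cycle genes had medians of -0.19 and -0.07, the second 0.39 under spike-in scaling, and developmental muscle genes 0.02 (-0.12 under median scaling) and 0.50, led by Tnnt2, cardiac troponin T (3.02 and 3.35).

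On the control diet 542 of 10755 measured genes were at least 2-fold higher and 821 at least 2-fold lower. On genistein the counts were 536 and 710 of 10810. In both diets 374 genes were higher and 513 lower, against 27.8 and 55.8 for independent lists, and 0 genes passed 2-fold in opposite directions. The balance of these counts depends on scaling. Higher genes made up 39.8% of those passing 2-fold on the control diet and 43.0% on genistein, but 28.8% and 32.3% under median scaling and 78.2% and 86.8% under spike-in scaling, which shifts the median of all genes to -0.11 and -0.08 or to 0.39 and 0.49 log2 units. The hybridisation controls, which are added to each sample before hybridisation, read lower on the denervated arrays by median log2 ratios of -0.39 on the control diet and -0.54 on genistein. The 3′ to 5′ signal ratio of actin, a sign of RNA integrity, was 2.08 and 2.32 in control and genistein sham muscle and 3.79 and 2.76 in denervated muscle, and that of Gapdh was 1.13 to 1.24 on all arrays.

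**Figure D2:**
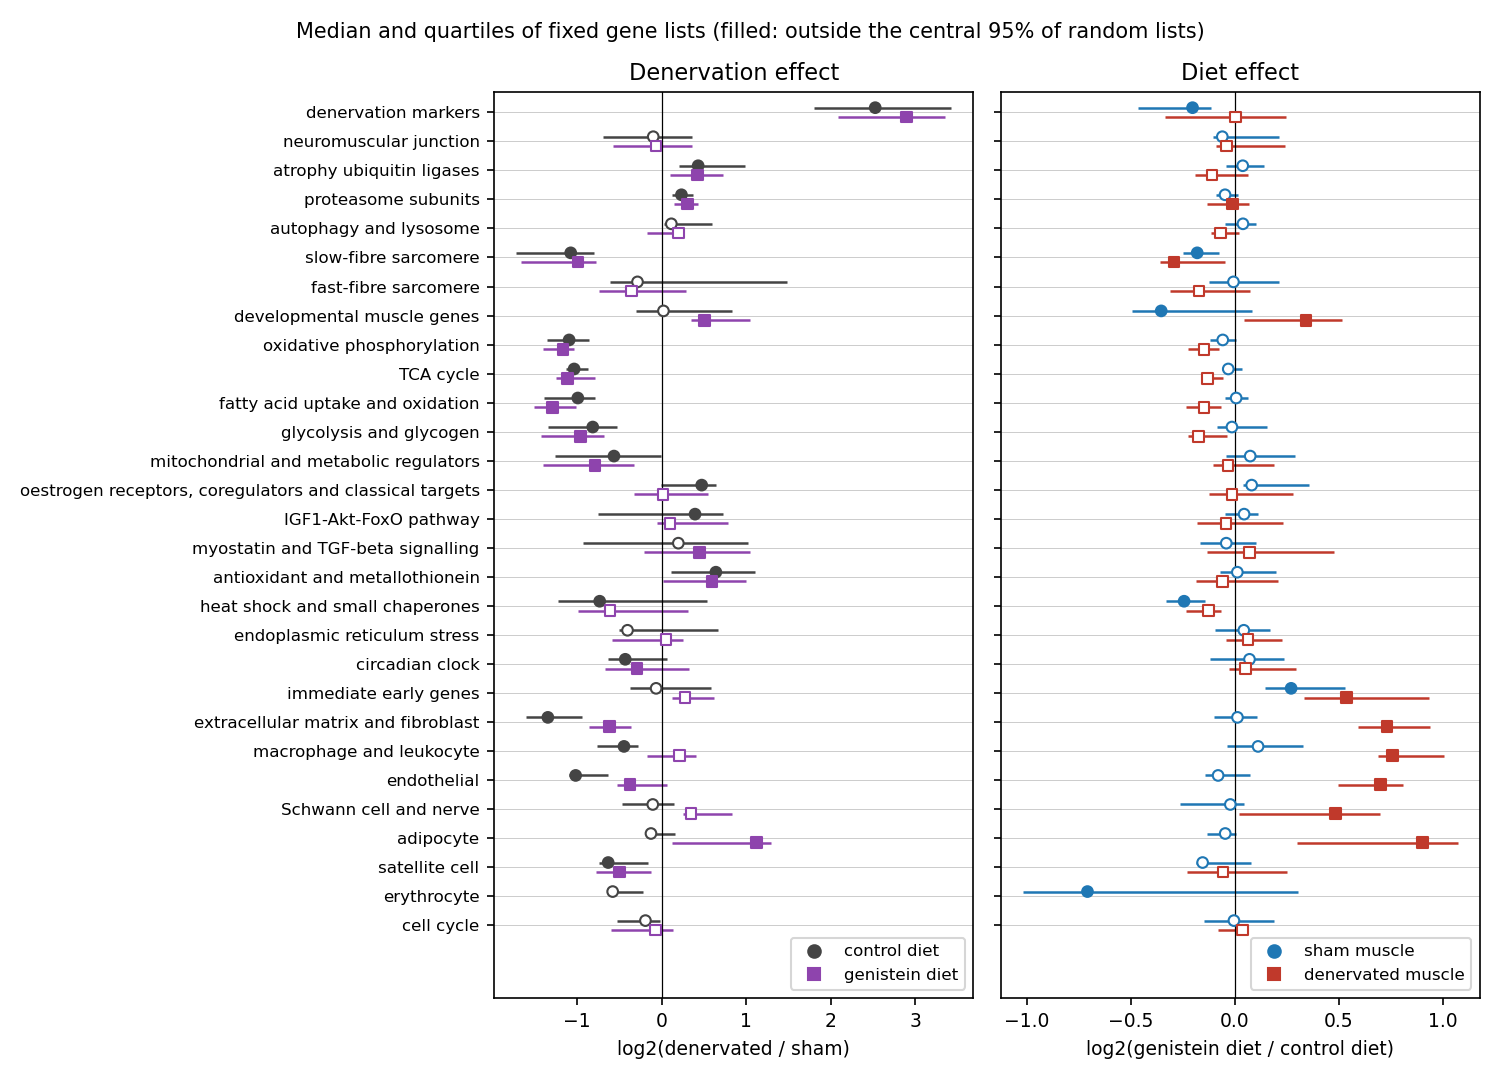
Median and quartiles of the log2 ratios of each gene list for the denervation effect (left, by diet) and the diet effect (right, by muscle), with filled symbols for medians outside the central 95% of 10000 matched random lists. On the right, extracellular matrix, leukocyte, endothelial, Schwann cell and adipocyte lists lie between 0.48 and 0.90 in denervated muscle and between -0.08 and 0.11 in sham muscle, where the extracellular matrix median of 0.01 changes sign under spike-in scaling.

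The next question is what genistein did in muscle with an intact nerve. In sham muscle few genes differed, 35 higher and 31 lower at 2-fold among 10819. The simulated arrays had 92 of 10851 unchanged genes past 2-fold in either direction, so scatter alone could give as many. That scatter was itself taken from these 2 sham arrays, so the comparison cannot separate diet from scatter. Mybph, myosin-binding protein H, was at 3597 units on the control diet and 646 on genistein (log2 ratio -2.48). The fast-fibre genes Mybpc2 (1.88, from 199 to 735 units) and Actn3 (1.25, from 230 to 549 units) were higher on genistein. The LIM protein genes Csrp2 (-1.51) and Pdlim4 (-1.36) were lower, reading 80.7 and 91.0 units on genistein, close to the floor.

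Groups shifted by small amounts in sham muscle. All 12 slow-fibre genes were below 0, with a median of -0.18 that was 0.00 under quantile normalization, and Pln, phospholamban, was at -0.79 and Csrp3, muscle LIM protein, at -0.74. Denervation markers had a median of -0.20 with 9 of 11 below 0, among them Ankrd1 (-0.73), Sln (-0.72) and Runx1 (-0.58). Developmental muscle genes had a median of -0.35, with Myh3, embryonic myosin, at -0.69 and Myh8, neonatal myosin, at 0.80. With the mean of probe sets this median came inside the central 95% of random lists. Heat shock and small chaperone genes had a median of -0.24, with 8 of 10 below 0 and Hspa1a at -0.59. All 10 measured immediate early genes were above 0 with a median of 0.27, led by Fos (0.90) and Zfp36 (0.62). The erythrocyte list had a median of -0.71 over 5 genes, with the beta globin Hbb at 15169 units on the control diet and 7469 on genistein. These 6 lists lay outside the central 95% of random lists. The other 23 did not, and their medians lay between -0.16 and 0.11.

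Cxcr5 (1.99), Cd1d1 (1.68), Fmo2 (2.83-fold), L3hypdh (1.48), Cish (1.46), Phf1 (1.38), Ins1 (1.33) and Klhl4 (1.16) were also among the 10 highest ratios, and Vax2 (-1.38), Cutal (-1.33), Ptpn23 (-1.31), Rbm7 (-1.27), Gapdhs (-1.20), Tmem97 (-1.17) and Spns2 (-1.16) among the 10 lowest. The dimmer side of each of these pairs read between 81.4 and 136 units, and the other probe set gave -0.25 for Fmo2, 0.44 for L3hypdh and 0.24 for Spns2. Of the always-named genes, Myh4 was at 0.81 (82 to 144 units), Trim63 at 0.02, Fbxo32 at 0.16, Foxo1 at 0.11, Foxo3 at 0.04, Igf1 at -0.05, Myh7 at -0.07, Myh2 at -0.11 and Myh1 at 0.09. Ppargc1a was higher by 0.54, with its 3 probe sets between 0.43 and 0.83, and Myog was lower at -0.35. With the floor at the 60th percentile 5 genes were higher and 3 lower. The log2 ratios had an SD of 0.27 across genes, close to the SD of 0.26 between probe sets of the same gene.

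The comparison at the centre of the study's title is the diet effect in denervated muscle. The genistein pool had more mRNA of genes that mark connective tissue, immune, vascular and fat cells. The 3′ to 5′ actin ratio also differed between these 2 pools (3.79 on the control diet and 2.76 on genistein). In denervated muscle 107 of 10479 genes were at least 2-fold higher on genistein and 13 lower. Beside these counts, 92 of 10851 unchanged genes passed 2-fold in the simulated arrays, whose scatter was drawn alike in both directions. Extracellular matrix and fibroblast genes had a median of 0.73 with 18 of 19 above 0, including Lox (1.31), Tnc (1.04), Fbn1 (0.97) and Fn1 (0.94). All 19 macrophage and leukocyte genes were above 0 (median 0.76), with Cd163 at 1.31, Ptprc at 1.30 and Itgb2 at 1.17. Adipocyte genes had a median of 0.90, with the desaturase Scd at 1.61, the lipid droplet protein Plin1 at 1.33 and Cfd at 1.08.

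Endothelial genes had a median of 0.70 with 10 of 11 above 0, including Kdr (0.91), Cldn5 (0.84) and Esam (0.83). Schwann cell and nerve genes had a median of 0.48, with Gap43 at 0.80. Each of these 5 lists lay, after rounding, at percentile 99.9 or higher of random lists, and in sham muscle their medians were -0.08 to 0.11. With no floor the Schwann cell list came inside the central 95%, and over the alternatives the adipocyte median ranged from 0.37 to 0.97. Immediate early genes were higher in all 10 members with a median of 0.54, led by Fos (1.37), Egr1 (1.06) and the phosphatase Dusp1 (0.99). Developmental muscle genes had a median of 0.34, which came inside the central 95% with the mean of probe sets, with Mymk, the myoblast fusion protein myomaker, at 1.15. Slow-fibre genes had a median of -0.29 with 9 of 12 below 0, including Myl2 (-0.65) and Tpm3 (-0.76 on its brightest probe set, with 11 probe sets from -0.76 to 1.07). The slow-fibre list came inside the central 95% under quantile normalization (-0.05) and with the mean of probe sets (-0.16). The proteasome list stood at percentile 98.2 with a median of -0.01 that became 0.06 under quantile and spike-in scaling. Beside these groups, oxidative phosphorylation genes had a median of -0.15 with 40 of 45 below 0, and glycolysis genes of -0.17, both inside the central 95% of random lists matched on expression. Satellite cell markers had a median of -0.06 (0.01 under spike-in scaling) and cell cycle genes of 0.04 (-0.05 under quantile normalization).

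**Figure D3:**
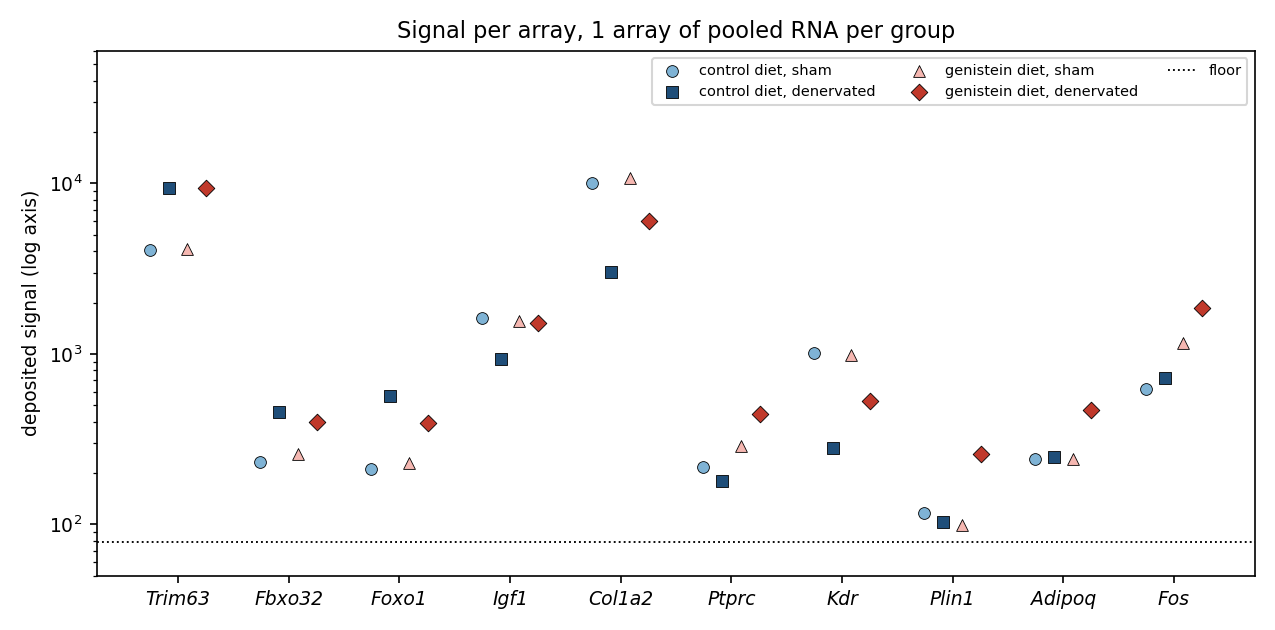
Deposited signal of 10 genes on each of the 4 arrays, on a log axis, with 1 point per pooled array and the floor as a dotted line. Trim63 reads 9461 and 9397 units in control and genistein denervated muscle, while Col1a2 reads 3027 and 6039 and Ptprc 180 and 444.

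Among the genes of muscle wasting in denervated muscle, Trim63 was at 9461 units on the control diet and 9397 on genistein (log2 ratio -0.01) and Fbxo32 at 456 and 398 (-0.20). Foxo1 was lower at 565 and 393 units (-0.53), and Foxo3 was at -0.04. Igf1 was at 929 and 1510 units (0.70), with its 3 probe sets between 0.50 and 0.70. Chrna1 was at -0.34, Chrng at 0.25, Myog at -0.08, Ppargc1a at 0.32, Myh4 at -0.73, Myh7 at -0.29, Myh2 at 0.24 and Myh1 at 0.13. The list medians were -0.11 for ubiquitin ligases (0.02 under quantile normalization), -0.07 for autophagy and lysosome (0.00 under spike-in scaling), -0.04 for the Akt and FoxO group (0.02 under spike-in scaling) and -0.01 for the oestrogen list (0.06 under spike-in scaling).

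Besides Scd, the highest ratios on genistein were Gda, guanine deaminase (1.62), the Fc receptor Fcgr2b (1.59), Pde8a (2.82-fold), Npy1r (1.43), the glucose transporter Slc2a3 (1.43), Rbp4, a retinol carrier made by fat cells (1.42), Ube3al1 (1.39), the lectin Clec4a3 (1.38) and the prostacyclin synthase Ptgis (1.37). The lowest were the aldo-keto reductase Akr1b8 (-2.31, from 1464 to 294 units), Abhd14a (-1.17), Itpk1 (-1.14), the carbonic anhydrase Car14 (-1.12), Dnm2 (-1.09), Cox7a1 (-1.06), Ttyh1 (-1.06), H4cl1 (-1.02), Tpd52l1 (-0.98) and Ins1 (-0.97). The other probe set gave 0.68 for Gda and -0.10 for Abhd14a. The dimmer side read between 84.4 and 143.4 units for Fcgr2b, Pde8a, Npy1r, Slc2a3, Rbp4, Ptgis, Abhd14a, Itpk1, Car14, Dnm2, Ttyh1, H4cl1 and Ins1. For Scd, Gda, Ube3al1, Clec4a3, Akr1b8, Cox7a1 and Tpd52l1 it read 209.1 units or more. Scatter of a single array, estimated from the sham arrays, had an SD of 0.35 at a mean log2 signal of 6.72 and 0.29 at 7.16. Ratios of the dimmer genes may therefore hold much scatter, as in sham muscle. Higher genes made up 89.2% of those passing 2-fold and 79.1% under quantile normalization, where 72 were higher and 19 lower. With the floor at the 60th percentile 31 genes were higher and 2 lower.

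The last comparison asks whether the denervation effect itself differed between the diets, as the ratio of the denervation ratios. Relative to the control diet, the response on genistein was more positive for 5 lists of markers of cells outside the fibre and less positive for a few fast-fibre genes. At 2-fold, 210 of 11151 genes were more positive on genistein and 79 less positive. The medians of this difference were 0.79 for extracellular matrix, 0.72 for leukocyte, 0.72 for endothelial, 0.55 for Schwann cell and 0.97 for adipocyte genes. For satellite cell, erythrocyte and cell cycle genes they were 0.06, -0.05 and 0.06, inside the central 95% of random lists, and under spike-in scaling the erythrocyte and cell cycle values changed sign, as the cell cycle value did under quantile normalization. The 3′ to 5′ actin ratio of 3.79 and 2.76 in the control and genistein denervated pools bears on this comparison too. Mybph had the largest difference (2.75), being at -0.30 after denervation on the control diet and 2.46 on genistein. Actn3 differed by -2.20, Mybpc2 by -2.18 and Myh4 by -1.54. The other Mybpc2 probe set gave a smaller difference, with 1.30 on the control diet and 0.19 on genistein after denervation.

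For these fibre genes the sham arrays contribute to the difference, since Mybph was lower and Actn3 and Mybpc2 higher in genistein sham muscle, and Myh4 differed by 0.81 between sham pools at 82 and 144 units. Developmental muscle genes had a median difference of 0.42 (0.19, inside the central 95% of random lists, with the mean of probe sets), with Myh3 at 1.28, and denervation markers 0.20, with Ankrd1 at 1.28. The slow-fibre list had a median difference of -0.13, inside the central 95% of random lists, with 8 of 12 members below 0. Its largest differences went the other way, Pln at 1.38 and Csrp3 at 1.04, and both genes were lower in genistein sham muscle. Immediate early genes stood at 0.39 and heat shock genes at 0.12. Fatty acid oxidation genes were at -0.19, a median that came inside the central 95% of random lists with the mean of probe sets. The oestrogen list was at -0.23, which was 0.04 with no floor. Igf1 was at 0.75, Foxo1 at -0.64, Fbxo32 at -0.36 and Trim63 at -0.03. Further genes with large differences were Spns2 (2.16), Rbp4 (2.00), Pdlim4 (1.81), F2rl1 (1.78), the endothelial factor Sox18 (1.73), Smap2 (1.67), the leukocyte tetraspanin Cd53 (1.62), Plin1 (1.57) and the endothelial receptor Tie1 (1.57). In sham muscle the 3 probe sets of Smap2 ranged from -0.95 to 0.12 and the other probe set of Spns2 gave 0.24. After denervation that Spns2 probe set gave -0.26 on the control diet and -0.50 on genistein, a difference of the opposite sign. In the other direction were Ins1 (-2.30), Cxcr5 (-2.24), Plagl2 (-1.75), Slc9a8 (-1.67), Lrrc46 (-1.66), Dpyd (-1.59) and Car14 (-1.50). Among these further genes of both directions, the dimmest array of each read between 84.2 (Plagl2) and 139.4 units (Cd53), except for Smap2 (251.5). Single-array scatter, estimated from the sham arrays, had an SD of 0.35 at a mean log2 signal of 6.72 and 0.29 at 7.16. A difference between the diets holds such scatter from each of its arrays, so scatter may make up part of these values. More positive genes made up 72.7% of those passing 2-fold and 61.5% under quantile normalization.

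Whether genistein scaled the whole denervation response down was examined across the 9362 genes above the floor on all arrays. The SD of the denervation log2 ratios was 0.73 on the control diet and 0.72 on genistein, a ratio of 0.982 against 0.989 to 1.01 in 100 simulated sets with no diet effect. Under quantile normalization the ratio was 0.999, inside that range, and with no floor 0.943. The 1161 genes picked as 2-fold changed on the control diet kept a median 0.895 of their log2 ratio on genistein, and the 1068 genes picked on genistein kept 0.913 on the control diet. The simulated sets gave means of 0.935 (range 0.921 to 0.952) and 0.936 (range 0.924 to 0.954), so both observed shares lay below the simulated ranges. The slope of the diet effect in denervated muscle on the denervation effect of the control diet was -0.109, and the simulation with no diet effect gave -0.0534 (range -0.0619 to -0.0452) because both quantities contain the control denervated array. The covariance was -0.0582 against -0.0289 simulated, a difference of -0.0293. These values are across genes, which are not independent replicates, and the scatter in the simulation was taken from the sham arrays alone. That scatter gives little weight to large differences, and the simulated levels already hold measured scatter. The simulated ranges may therefore be too narrow or displaced.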

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

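The test on the poly-A controls was chosen, and array brightness was considered without a test, after the result was seen. No difference in this part was tested with replicates. The median of the developmental muscle list lay on opposite sides of 0 for diet in the 2 muscles. It was -0.35 in sham muscle, with 4 of 7 members below 0, and 0.34 in denervated muscle, with 5 of 7 above 0, both outside the central 95% of random lists. Myh3, embryonic myosin, was at -0.69 and 0.59, Igf2 at -0.42 and 0.24, and Tnnt2 at 0.02 and 0.34, whereas Myh8 was higher in both (0.80 and 0.44). With the mean of a gene's probe sets both medians came inside the central range.

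Spns2, a sphingosine phosphate transporter, was the named gene that passed 2-fold with diet in opposite directions, at -1.16 in sham muscle (292 to 131 units) and 1.01 in denervated muscle (115 to 230 units). That difference was not tested either, and its other probe set gave 0.24 in sham muscle.

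Probe sets without 1 named gene were left out of the report's counts, yet 197 of them were at least 2-fold higher after denervation in both diets and 158 at least 2-fold lower, with 0 in opposite directions. The diet contrasts gave 46 such probe sets in sham muscle either way, and 37 higher and 6 lower in denervated muscle.

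The spike-in controls, which are foreign transcripts, read lower on both denervated arrays. Scaling to the authors' trimmed mean is argued against as the source, since under median scaling the hybridisation controls were still lower by a mean log2 ratio of -0.60. A larger mRNA share of total RNA would lower the poly-A controls, assumed here to be added to the RNA before labelling, more than the hybridisation controls. The poly-A shift minus the hybridisation shift was, however, 0.010 (standard error 0.070). That standard error is over probe sets, several of which read the same transcript, so it may overstate the precision. A scan brighter by the same factor for all probe sets is argued against. Such a factor drops out, since every array has a trimmed mean of 500.2, and it could not lower the controls relative to the genes. More labelled target on the denervated arrays remains a possible explanation that cannot be told apart from a difference between the muscles. The only value at hand is the hybridisation shift itself, a mean of -0.47 over the diets, and unscaled brightness was not analysed. No other biological explanation was tested.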

How the results depend on the processing

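Spike-in scaling was chosen after the data were seen. No paired analysis was possible because each group has 1 array and so the groups share fewer than 2 replicate numbers. An additive fit of denervation and diet, which leaves 1 residual degree of freedom, was not run, since that residual is the difference between the diets compared here. The floor settings show that signal over background limits the counts of the denervation contrasts and of the diet contrasts. Of 108 gene counts under alternatives, 61 stayed within 1.5 times the main count and 47 did not. With no floor, the higher and lower counts were 1371 and 1920 for denervation on the control diet, 1300 and 1661 on genistein, 591 and 842 in both diets, 920 and 822 for diet in sham muscle, 982 and 723 in denervated muscle, and 1403 and 1201 for the difference between diets. With the floor at the 20th percentile, 1318 genes were lower on the control diet and 817 higher and 1088 lower on genistein, with 362 and 320 for diet in sham muscle, 396 and 177 in denervated muscle and 762 and 510 for the difference. With the floor at the 60th percentile the diet counts were 5 and 3 in sham muscle, 31 and 2 in denervated muscle and 42 and 12 for the difference. A lower floor admits more dim genes, whose ratios scatter more. At 1.5-fold the counts were 1508 and 1906 on the control diet, 1565 and 1663 on genistein, 969 and 1173 in both, 289 and 270 for diet in sham muscle, 652 and 188 in denervated muscle and 942 and 496 for the difference. Spike-in scaling gave 1350 and 377 on the control diet, 1750 and 266 on genistein, 990 and 220 in both diets and 164 higher for diet in denervated muscle, through its shift of all genes. The mean of probe sets left 6 genes lower for diet in denervated muscle, and the cause was not tested. The slope of the diet effect on the denervation effect was -0.29 with no floor.

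Among list medians outside the central 95% of random lists, those that changed sign were the oestrogen list for the difference between diets (0.041 with no floor), the proteasome list for diet in denervated muscle (0.057 under quantile normalization and 0.058 under spike-in scaling), and under spike-in scaling the clock list (0.18) and the endothelial list (0.046) for denervation on genistein. Beyond the uniform shift of spike-in scaling, the cause was not tested. Of 61 list medians outside the central 95%, 45 stayed outside under every alternative and 16 did not. Under quantile normalization those inside were the ubiquitin ligase list for denervation in both diets, the slow-fibre list for denervation on genistein and for diet in both muscles, and the oestrogen list for the difference between diets. With the mean of probe sets they were the ubiquitin ligase list again, the developmental list for diet in both muscles and for the difference, the slow-fibre list for diet in denervated muscle, the fatty acid list for the difference, and the oestrogen and clock lists for denervation on the control diet. The oestrogen, clock, satellite cell and Schwann cell lists lost theirs under floor settings, and the proteasome list for diet in denervated muscle did without probe sets that may cross-hybridise. For named genes 176 values moved by more than the SD between probe sets of a gene and 1179 by less, and 0 of those past 2-fold changed sign. The diet effect in denervated muscle kept its place outside the central 95% under all 8 alternatives for the extracellular matrix (0.72 to 0.82), leukocyte (0.57 to 0.83), endothelial (0.57 to 0.77) and adipocyte lists (0.37 to 0.97), and the Schwann cell list lost it with no floor.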

Other observations

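The tests of quantile scaling, of a lower fibre share and of RNA integrity were chosen after the result was seen, and the genes in this paragraph were picked after their values were seen. A few genes differed with diet by a like amount in both muscles, which come from opposite legs of the same rats. The genes at least 2-fold higher on genistein in sham and in denervated muscle were Cish, a feedback inhibitor of cytokine signalling (1.46 and 1.34), Fmo2 (2.83-fold and 2.21-fold on its brightest probe set, while the other gave -0.25 in sham muscle), Ccdc68 (at least 1.29 and at least 1.13) and Myo1f (1.15 and at least 1.12). Values without the word fold are log2 ratios. These 4 genes compare with 0.338 for independent lists, and 0 genes were 2-fold lower in both. The figure of 0.338 gives every gene the same chance of passing and may be too low. Diet counts fell with a higher floor, so dim genes make up much of them. Fmo2 read 85.3 units in control sham and 97.1 in control denervated muscle, close to the floor. Ndufs4, a subunit of respiratory complex I, was at 3587 and 7518 units in control and genistein sham muscle (1.07) and at 4150 and 8076 in denervated muscle (0.96), against an oxidative phosphorylation list median of -0.06 and -0.15. The immediate early genes Fos (0.90 and 1.37) and Egr1 (0.59 and 1.06) were higher on genistein in both muscles. The beta globin Hbb (-1.02 and -0.66) and Alas2, the erythroid haem synthesis enzyme (-0.71 and -0.76), were lower in both.

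The members of the extracellular matrix, leukocyte, endothelial, Schwann cell and adipocyte lists were pooled after these lists were seen to be higher on genistein in denervated muscle. Their median relative to all genes was -0.73 (standard error 0.12) after denervation on the control diet. On genistein it was -0.15 (standard error 0.13), where 30 of 69 members lay above the median of all genes. These standard errors are over genes on 1 pair of arrays and do not measure variation between pools or rats. Single lists differed from that pooled value, as the adipocyte list had medians of -0.13 and 1.12 and the Schwann cell list of -0.11 and 0.35. In the diet contrast of denervated muscle, 61 of 67 pooled members lay above the median of all genes. The most abundant of these markers went with it, Dcn from 8478 units on the control diet to 13946 on genistein, Col3a1 from 4998 to 7832 and Lum from 3987 to 6986. Of the lists left out of the pool, the satellite cell list had 4 of 8 members above the median of all genes. The erythrocyte list had 1 of 4 members above 0, and the cell cycle list 4 of 7.

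That pattern, markers of cells outside the fibre higher on genistein in denervated muscle, has technical and biological candidates. Scaling is argued against as the whole of it. Relative to all genes, the median of these markers was 0.72 (standard error over genes 0.061) under quantile normalization, which moves genes by different amounts. A lower share of fibre RNA that raises all other cell types alike was not decided. The 5 lists lay within 2 standard errors of each other (gap 0.42 against 0.61). They were picked for being higher in this contrast, so their closeness says little on whether all cell types rose alike. Fibre genes were at -0.14, with 23 of 127 above the median of all genes, a comparison not matched on expression. Among matched random lists, the fast-fibre, oxidative phosphorylation, citric acid cycle, fatty acid and glycolysis lists lay inside the central 95%. The slow-fibre list lay outside, but came inside under quantile normalization and with the mean of probe sets. The satellite cell list (-0.05), added after the result was seen, lay 0.96 below the adipocyte list (0.91), against 0.59 for 2 standard errors of that gap. That limit is for a single pair of lists, whereas the highest and the lowest list were taken, and its standard errors are over genes. A difference in RNA integrity cannot be told apart from the diet, because the 3′ to 5′ ratio was higher in the control pool by 0.45 log2 units for actin (3.79 against 2.76) but was alike for Gapdh (1.14 and 1.13). A lower fibre share, with or without a change in satellite cells, stays open with 1 array per group. So do a change in the cell types that rose, an effect of genistein on them, and a difference in dissection or pooling between the 2 pools, all untested.

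A second pattern is that genes picked as changed by denervation on the control diet changed less on genistein, as they would if the diet damped the response. Picking genes on 1 set of arrays shrinks their ratios on the other set whichever set is used, as regression toward the mean, and the mirror picked on genistein kept a share only 0.0177 higher on the control diet, under the bound of 0.05 set beforehand. The observed shares of 0.895 and 0.913 nevertheless lay below those of all 100 simulated sets with picking and no diet effect (0.921 to 0.952 and 0.924 to 0.954), and picking cannot be told apart from differences of single genes between the diets because the simulated scatter came from the sham arrays alone. In a simulation built with damping on genistein to 0.8 of the effect, the shares were 0.747 for genes picked on the control diet and 1.14 for the mirror, unlike those observed. A smaller damping of the whole response, for which the ratio of SDs was 0.982 but 0.999 under quantile normalization, and damping of single genes, such as Foxo1 (-0.53) in denervated muscle, stay open.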
